A study of Mus musculus with 4 samples.

How the data were processed

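The data were droplet single-cell RNA libraries of liver cells from 2 Control and 2 Cyr61 KO samples of male mice on a NASH diet. Per the labels' protocols, livers were kept in serum with 10% DMSO, thawed, enzymatically digested with mechanical dissociation and passed over a column that removes dead cells. The authors deposited raw UMI counts per gene and barcode, made with Cell Ranger 3.1.0 against mm10 per the submitters' processing notes, and the lowest total per barcode was 500 UMIs. No file held cell type annotations, so cells were named anew. Of 32285 gene identifiers, 99.6% matched GENCODE M21 (GRCm38), from which coordinates were taken. The libraries were not duplicates of each other (chi-squared per degree of freedom 51.7 between the Control and 35.0 between the KO libraries).

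Cells were kept with at least 500 UMIs, at least 250 genes and at most 25% UMIs of mitochondrially encoded genes. Doublets were scored per library with Scrublet (as in scanpy 1.11.5, expected rate 0.06). It marked 0.042%, 0% and 0.014% of Control 1, Control 2 and KO 1, under the 0.5% set as a minimum, so there the highest scores were removed at a rate of 0.8% per 1000 barcodes (183, 411 and 415 cells). In KO 2 it marked 1.74% (88 cells), which were removed, so that doublets were treated by different rules in the KO libraries. The kept cells were clustered with 2000 variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden resolution 1.0, without batch integration. Clusters were named "X-like" from markers of 17 cell types and stayed unnamed with under 3 detected markers or leading genes that went against the name.

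Raw counts were summed per library and class. A class was tested where each library had at least 20 of its cells, which 8 classes met; hepatocyte-like cells and the unnamed clusters did not. The main test was edgeR 4.0.16 (TMM, filterByExpr, glmQLFit and glmQLFTest, Benjamini-Hochberg adjusted p below 0.05), KO against Control with no covariate. Cell shares were tested with the same model on cell numbers with the kept cells as library size, beside an exact two-sided permutation test. A set of 27 gene lists was tested with camera (limma 3.58.1, preset correlation 0.01, also with an estimated correlation) where at least 4 members were measured. The tests, markers, lists and alternatives were fixed before the data were examined, except where the text says otherwise.

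The named genes were set by rule. In macrophages these were Cyr61 (Ccn1), Syk, Nfkb1, Rela, Pdgfa and Pdgfb, then the 10 higher and 10 lower genes with the smallest p among those that passed with both KO libraries on one side of both Control libraries, and up to 4 members per list. In other classes they were the 3 higher and 3 lower genes by the same rule. Immunoglobulin and T cell receptor segments were counted but not named. Folds against a group with 0 counts are lower bounds against 3 counts over the group. Intervals (95%) and such bounds cover counting error only.

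The pipeline was tested on simulated data with 200 changed genes per class. In macrophages, edgeR recovered 39% of 2-fold and 90% of 4-fold changes over 7042 genes, with 3.01% false calls, and DESeq2 1.42.0 recovered 19% and 65%. In T cells, edgeR recovered 66% and 98% over 11476 genes with 1.80% false calls, and DESeq2 41% and 88%. A simulated 2-fold lower MHC class II list was called by camera with the preset correlation in both classes and in neither with an estimated one, and 0 other lists were called. The simulated genes were drawn independently with a common dispersion. The 0 other lists therefore do not show that the preset correlation guards against false calls where genes move together. A call with the preset correlation alone is thus uncertain, and absence of one with an estimated correlation says little at this sample size.

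The alternatives were DESeq2, relative log expression size factors, no filter on low counts, hepatocyte and haemoglobin genes left out, the replicate number as a block, at most 10% mitochondrial UMIs, at least 1000 UMIs, doublets kept, Leiden resolution 2.0, TMM over the classes for shares, and each library left out in turn. Fits without the C1q-led macrophages or on one finer macrophage cluster, and gene lists in other classes, were added after seeing the data. Python 3.11.15 and R 4.3.3 were used.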

Results

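Droplet single-cell RNA sequencing (10x Genomics) measured transcripts of cells from livers of male mice aged 24 weeks that had received a NASH diet for 12 weeks. Such a diet brings on fatty liver with inflammation and scarring. There were 2 Control libraries and 2 libraries labelled as Cyr61 knockout (Cyr61 KO), all on a strain with a floxed Cyr61 gene, and the labels do not state in which cells the gene was deleted. The matrices held 4852 and 7253 barcodes in Control 1 and 2, and 7241 and 5373 barcodes in KO 1 and 2. Their total UMIs (unique molecular identifiers, each standing for 1 captured transcript) were 8290677 and 20537236 in Control, and 17187561 and 17925516 in KO. After the filters, 4535, 6679, 6742 and 4977 cells were kept, in the same order, with medians of 1203, 2203, 1847 and 2837 UMIs per cell. All fold changes are KO over Control, with the standard error (SE) of the log2 value and n = 2 libraries per group. Nothing in the labels says whether each library came from 1 separate animal, so p-values measure only the spread between these libraries.

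The first question was whether the targeted gene was lower in the KO libraries. Cyr61, a secreted matrix-associated protein, is listed under its current symbol Ccn1 (ENSMUSG00000028195, a protein-coding gene on chromosome 3, 145646976 to 145649981, minus strand, GRCm38). Over all barcodes, Ccn1 had 184 and 149 UMIs in Control 1 and 2, and 0 and 12 UMIs in KO 1 and 2. These were 22.2 and 7.26 CPM (counts scaled to a common library total) in Control and 0 and 0.669 CPM in KO, where the count of 0 in KO 1 allows up to 0.1745 CPM. Summed over the kept cells, Ccn1 fell with a log2 fold change of -5.21 ± 0.94 (SE, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0315). With DESeq2 it was -5.33, with an adjusted p of 0.0933.

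Nearly all Ccn1 transcripts came from 1 cluster, whose cell type was left open. Of 324 Ccn1 UMIs in kept cells, 320 (98.8%) lay in cluster 4, which matched mesothelial markers best but was led by fibroblast genes such as Dcn and Col3a1, and stayed unnamed. This cluster had 315 and 65 cells in Control 1 and 2, and 1 and 2 cells in KO 1 and 2. Among its Control cells, 90 of 380 (23.7%, exact binomial 95% interval 19.5 to 28.3%) held a Ccn1 UMI at a median depth of 2127.5 UMIs, against 1 of 5559 Control T cell-like cells (0.018%) at a median depth of 1706 UMIs. In KO 2, 1 of the 2 cells of this cluster held a Ccn1 UMI, and the cluster accounted for 11 of that library's 12 UMIs. Monocyte-derived macrophage-like cells held 1 Ccn1 UMI in Control 1 and 0 in the other 3 libraries, and hepatocyte-like cells held 0 in all 4. The hepatocyte-like cells were only 6 and 11 barcodes in Control 1 and 2, where 3 counts over the group would stand at 111 CPM. Their count of 0 therefore does not show that hepatocytes lack Ccn1. The lower total followed the near absence of cluster 4 from the KO libraries. The 3 KO cells of that cluster showed no lower level per cell: the 1 cell with Ccn1 put the cluster at 1352 CPM in KO 2, against 121 and 148 CPM in Control 1 and 2, and KO 1 had 0 UMIs in 1 cell. A single cell decides little, so Ccn1 is a weak check of the genotype labels.

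**Figure D1:**
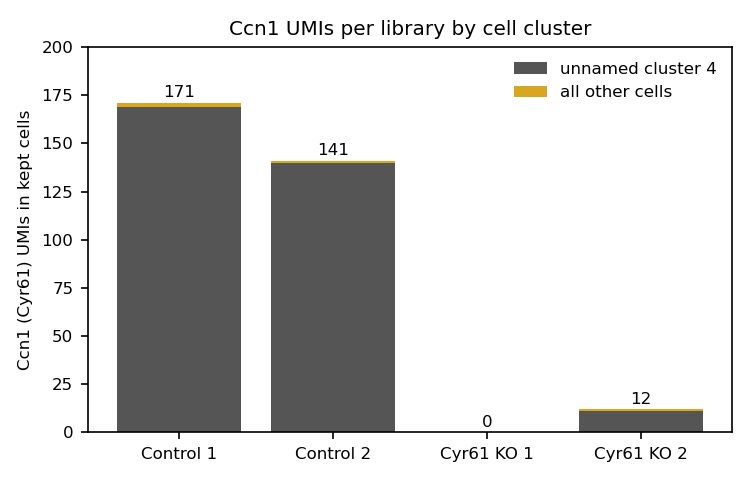
Ccn1 (Cyr61) UMIs in the kept cells of each library, split into unnamed cluster 4 and all other cells. The Control libraries held 171 and 141 UMIs and the KO libraries 0 and 12.

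The next question was which cell types the livers yielded in each group. The cells formed 21 clusters, grouped into 9 named classes and 3 unnamed clusters. Immune cells made up most of them, with T cell-like cells at 48.9 ± 5.0% (SD) of Control cells and 48.3 ± 3.05% of KO cells. Conventional dendritic-like cells fell from 7.14 ± 4.90% in Control to 0.958 ± 0.180% in KO (log2 -2.90 ± 0.64, SE, edgeR adjusted p = 0.0292), which did not pass with doublets kept (edgeR adjusted p = 0.0587). Neutrophil-like cells fell from 2.30 ± 0.0350% to 1.08 ± 0.0615% (log2 -1.09 ± 0.26, edgeR adjusted p = 0.0314), a call lost at 1000 UMIs (edgeR adjusted p = 0.173) and at resolution 2.0 (edgeR adjusted p = 0.0698). Hepatocyte-like cells rose from 0.149 ± 0.0229% to 0.697 ± 0.190% (log2 2.21 ± 0.38, edgeR adjusted p = 0.0233). Unnamed cluster 4 fell from 3.96 ± 4.22% to 0.0275 ± 0.0179% (log2 -7.13 ± 1.46, edgeR adjusted p = 0.0292), and with doublets kept the cluster with its leading genes did not pass (edgeR adjusted p = 0.0587). Unnamed cluster 20, led by the predicted genes Gm10800, Gm10801 and Gm10719, fell from 0.758 ± 0.331% to 0.0249 ± 0.00677% (log2 -4.77 ± 0.59, edgeR adjusted p = 0.0133).

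The other 7 classes did not pass. Monocyte-derived macrophage-like cells were 8.68 ± 2.28% of Control and 3.98 ± 1.14% of KO cells (edgeR adjusted p = 0.0784). B cell-like cells were 19.7 ± 8.89% and 34.4 ± 3.15% (edgeR adjusted p = 0.187), and natural killer or innate lymphoid-like cells were 5.89 ± 1.11% and 8.72 ± 0.855% (edgeR adjusted p = 0.187). Plasmacytoid dendritic-like cells (edgeR adjusted p = 0.387), cycling cell-like cells (0.534), unnamed cluster 18 (0.648) and T cell-like cells (0.950) showed no detectable difference. Cluster 18, led by B930036N10Rik, 2900060B14Rik and Arc, was 0.374 ± 0.0633% of Control and 0.324 ± 0.00342% of KO cells. No cluster met the markers of Kupffer, stellate or fibroblast, or endothelial cells. The exact two-sided permutation test gave p = 0.333 for each of the 5 classes that changed, the smallest value 2 against 2 libraries allow. Leaving out KO 1 took the changed classes from 5 to 0, leaving out KO 2 to 2, and leaving out Control 2 to 9. Shares also depend on freezing, digestion and dead cell removal, and cluster 4 ranged from 6.95% in Control 1 to 0.973% in Control 2.

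**Figure D2:**
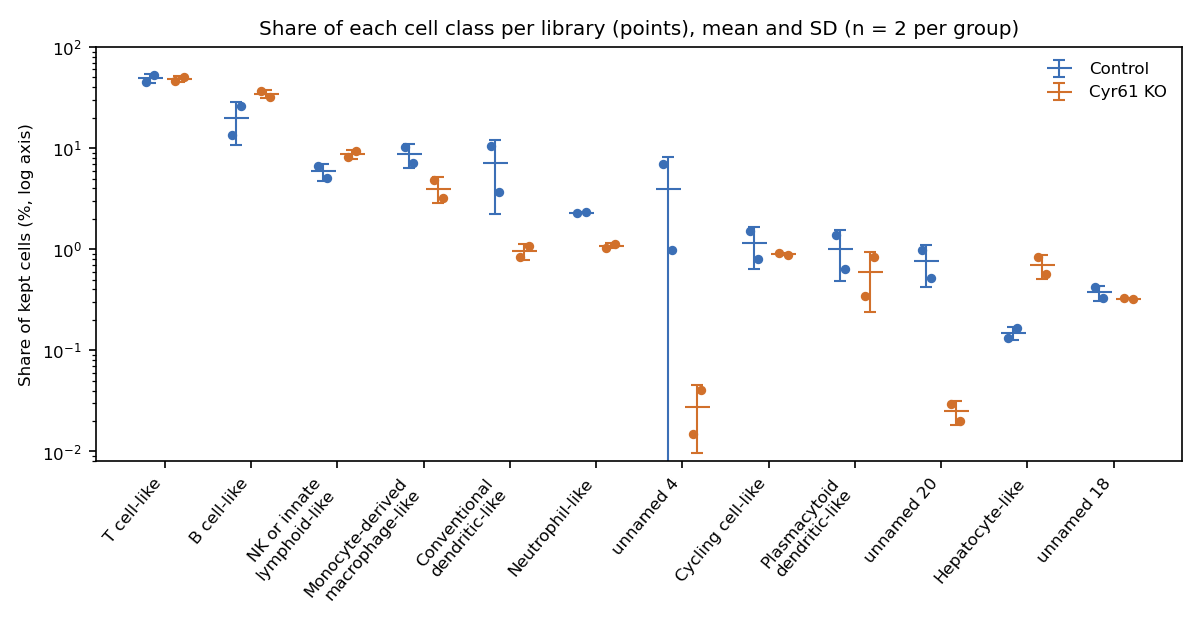
Share of kept cells in each class per library, on a log axis, with points for libraries and lines for the mean and SD (n = 2 per group). Conventional dendritic-like and neutrophil-like cells and unnamed clusters 4 and 20 lie lower in KO and hepatocyte-like cells higher, and the lower end of the Control bar of unnamed 4 lies below the axis.

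**Figure D3:**
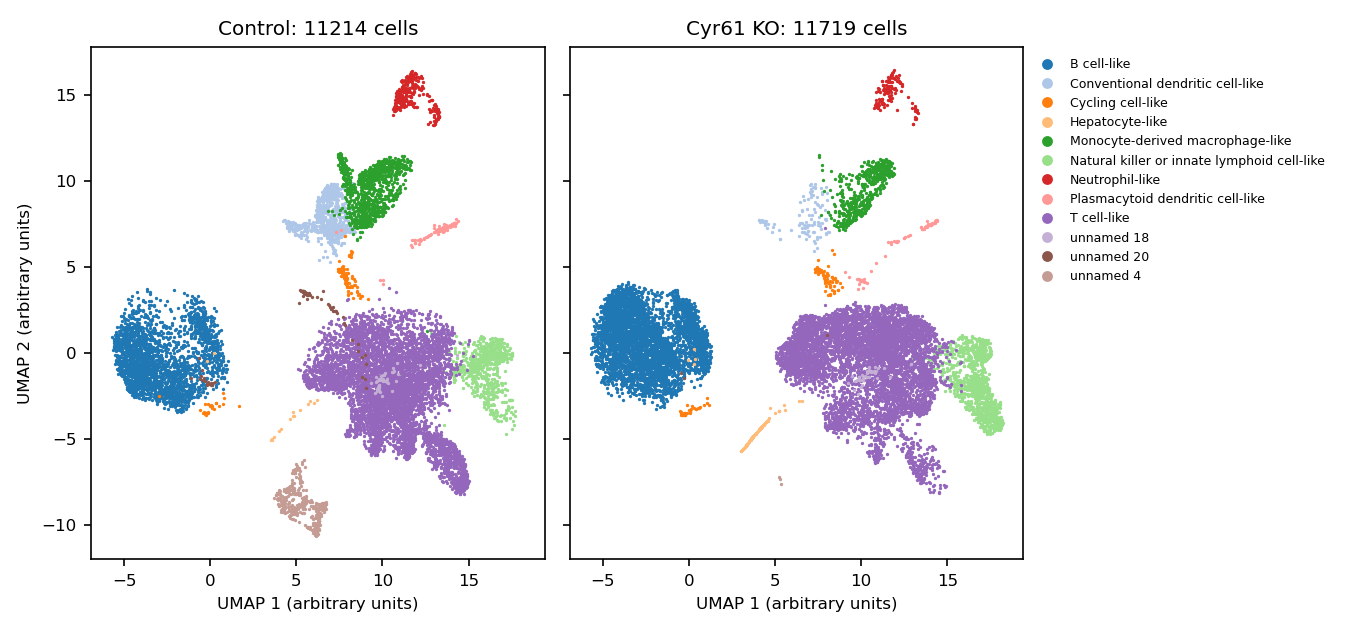
Map of the kept cells by UMAP (arbitrary units) for 11214 Control and 11719 KO cells, coloured by class. The island of unnamed cluster 4 is filled in Control and holds 3 cells in KO.

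The main comparison asked what differed between the KO and Control libraries in the class nearest to monocyte-derived macrophages, the cell type that the study's title names. The markers that named this class include monocyte genes, and monocytes were not told from macrophages within it. In monocyte-derived macrophage-like cells (467 and 472 cells in Control 1 and 2, and 323 in KO 1, with fewest in KO 2), 138 of 7042 genes changed, 23 higher and 115 lower in KO (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). The complement C1q chain genes, 6 of 12 measured MHC class II genes and 10 of 22 genes of lipid-associated macrophages fell, and the genes that rose included Hpgd and the monocyte gene F13a1. C1qc fell from 481 ± 225 CPM (SD) to 21.2 ± 18.8 CPM (log2 -4.43 ± 0.42, SE, edgeR adjusted p = 3.98e-05). H2-Eb1, a chain of the antigen-presenting MHC class II molecules, fell from 1335 ± 626 to 167 ± 38.8 CPM (log2 -2.99 ± 0.29, edgeR adjusted p = 3.98e-05). Hpgd, a gene of an enzyme that degrades prostaglandins, rose from 47.5 ± 1.28 to 139 ± 41.5 CPM (log2 1.55 ± 0.24, edgeR adjusted p = 0.00211).

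The other genes that fell with the smallest p included Emp1, a membrane protein (log2 -4.01 ± 0.30), Hebp1, a haem-binding protein (-4.61 ± 0.43), C1qb (-3.99 ± 0.39), Saa3, an inducible serum amyloid (-4.62 ± 0.46), and Spp1, the secreted phosphoprotein osteopontin (-3.90 ± 0.42). Apoe, the lipid carrier apolipoprotein E, fell by 2.10 ± 0.23 and H2-Ab1 fell by 2.14 ± 0.23 on the log2 scale, and Apoe went from 7469 ± 2980 to 1742 ± 63.3 CPM. Cd38, an enzyme on the cell surface, had 136 UMIs in Control and 2 in KO, a ratio of 48.9 with a counting interval of 13.3 to 408. Their edgeR adjusted p-values were 8.84e-05 or lower. Other genes that rose included Stxbp6 (1.60 ± 0.24), Rfx2 (2.03 ± 0.34), Cd177 (1.60 ± 0.29), the clotting factor subunit gene F13a1 (1.23 ± 0.24), Plec (0.95 ± 0.20), Myadm (0.85 ± 0.18), Pdlim1 (1.01 ± 0.22) and Nhsl2 (1.45 ± 0.32). Their edgeR adjusted p-values ran from 0.00186 to 0.0263. C1qb, Apoe and F13a1 were also among the 10 genes that led the cluster. Leaving out Control 2 or KO 1 gave 302 or 264 changed genes in place of 138, and DESeq2 gave 61. With DESeq2, Spp1 (adjusted p = 0.221), Plec (0.171), Myadm (0.0586), Pdlim1 (0.179) and Nhsl2 (0.140) did not pass, while Emp1, Hebp1, C1qb, Saa3, Apoe, H2-Ab1, Cd38, Stxbp6, Rfx2, Cd177 and F13a1 passed.

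**Figure D4:**
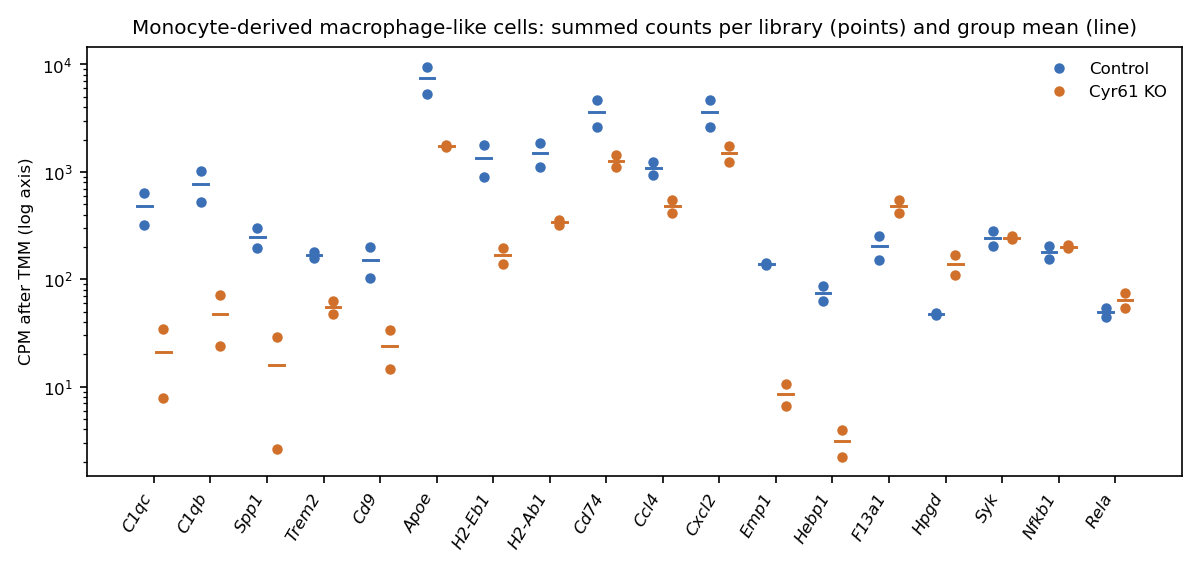
CPM of selected genes in monocyte-derived macrophage-like cells, on a log axis, with points for libraries and a line for each group mean (n = 2 per group). C1qc, H2-Eb1, Emp1 and Hebp1 separate the groups widely, while Syk, Nfkb1 and Rela overlap or nearly so.

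The title places SYK, NF-kappaB and PDGF signalling downstream of CYR61. None of the measured genes Syk, Nfkb1, Rela and Pdgfb passed the test in this class. Transcript levels do not measure the activity of these proteins, so they do not test the signalling itself. In the simulation of this class, edgeR recovered 39% of 2-fold changes. Syk, a kinase that signals from immune receptors (chromosome 13, 52583173 to 52648792), was at 244 ± 53.5 CPM in Control and 245 ± 12.4 CPM in KO (log2 0.02 ± 0.20, edgeR adjusted p = 0.985). Nfkb1 (log2 0.15 ± 0.19, edgeR adjusted p = 0.833) and Rela (0.36 ± 0.25, edgeR adjusted p = 0.633) encode NF-kappaB subunits. Pdgfb, a ligand that stimulates stellate cells, was at 42.4 ± 3.28 CPM in Control and 19.8 ± 18.6 CPM in KO (log2 -1.14 ± 0.44, edgeR adjusted p = 0.273), with 6 UMIs in KO 1 and 25 in KO 2. Pdgfb did pass as lower at 10% mitochondrial UMIs (log2 -1.65, edgeR adjusted p = 0.0418) and without the filter on low counts (-1.13, edgeR adjusted p = 0.0389). It also passed with the replicate number as a block. Without KO 2 its log2 value was -2.63. Ccn1 and Pdgfa had too few counts for the test in this class. Of 23 measured SYK and immunoreceptor genes, 0 rose and 1 fell, Blnk (log2 -2.76 ± 0.68), and the list did not pass (camera adjusted p = 0.337). Itgax (-0.81), Plcg2 (0.53) and Cd14 (-0.49) did not pass.

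Of 29 measured NF-kappaB targets, 0 rose, 3 fell and 26 did not pass; adjusted over the list alone, 1 rose and 5 fell. The chemokine genes Ccl4 (log2 -1.17 ± 0.21) and Cxcl2 (-1.29 ± 0.24) fell, as did Bcl2a1b (-1.11 ± 0.23), whose near-identical copies make its count uncertain (edgeR adjusted p = 0.00579, 0.00889 and 0.0160). Birc3 was at 0.74 ± 0.21 (edgeR adjusted p = 0.102). The list was lower with a median log2 fold change of -0.28 (camera adjusted p = 0.00575; adjusted p = 0.202 with an estimated correlation). Of the 6 PDGF ligand and receptor genes, Pdgfb was measured, too few for a list test.

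Of 22 measured genes of lipid-associated macrophages, which take up lipid and gather around dying hepatocytes, 0 rose and 10 fell (14 adjusted over the list alone). The median log2 fold change was -0.93 (camera adjusted p = 1.40e-21; adjusted p = 0.135 with an estimated correlation). Besides Spp1 and Apoe, the lipid receptor gene Trem2 (-1.61 ± 0.21) and Cd9 (-2.57 ± 0.36) fell. Of 12 measured MHC class II genes, 0 rose and 6 fell (8 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 4.29e-17; adjusted p = 0.195 with an estimated correlation). H2-Aa fell by 2.04 ± 0.25 and the invariant chain gene Cd74 fell by 1.52 ± 0.24 on the log2 scale. Of 16 measured profibrotic secreted factors, 0 rose and 6 fell (8 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 6.81e-11; adjusted p = 0.135 with an estimated correlation). Among them, the growth factor gene Igf1 (-3.69 ± 0.68) and the matrix protease gene Mmp14 (-2.19 ± 0.45) fell, and Mmp12, a macrophage elastase, was at least 23.7-fold lower, with 99 UMIs in Control and 0 in KO.

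Of 7 measured Kupffer cell genes, 0 rose and 3 fell (6 adjusted over the list alone), with a median of -1.16 (camera adjusted p = 4.72e-09; adjusted p = 0.135 with an estimated correlation). They were Cd38, the receptor gene Axl (-1.41 ± 0.28) and Cd5l, whose 37 Control UMIs and 1 KO UMI gave a ratio of 26.6 (counting interval 4.49 to 1079), while Nr1h3 was at -1.16 ± 0.35 (edgeR adjusted p = 0.124). Of 11 genes of endothelial inflammation and adhesion, 0 rose and 3 fell (5 adjusted over the list alone; camera adjusted p = 6.92e-09; adjusted p = 0.195 with an estimated correlation). These were Spp1, Cd9 and Cxcl16 (-2.16 ± 0.35), of which Spp1 and Cd9 also stand in the lipid-associated list. Of 4 acute phase genes, 2 fell, Saa3 and Igf1, and C3 (0.56 ± 0.19) and Hp (-0.06 ± 0.19) did not pass (camera adjusted p = 7.06e-05; adjusted p = 0.195 with an estimated correlation). Adjusted over the list alone, 1 acute phase gene rose and 2 fell. Of 8 cell cycle genes, 0 rose and 2 fell (4 adjusted over the list alone; camera adjusted p = 6.16e-05; adjusted p = 0.220 with an estimated correlation), Stmn1 (-2.25 ± 0.48) and Ube2c (43 UMIs against 2, ratio 15.5, counting interval 4.03 to 132). Of 11 genes of lipid synthesis and storage, 0 rose and 2 fell (4 adjusted over the list alone; camera adjusted p = 0.000937; adjusted p = 0.220 with an estimated correlation), the fatty acid transporter gene Cd36 (-1.77 ± 0.40) and the lipid droplet gene Plin2 (-0.88 ± 0.21).

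Genes of cholesterol synthesis and uptake went the other way. Of 12 measured, 2 rose and 0 fell (6 rose adjusted over the list alone), with a median of 1.05 (camera adjusted p = 2.47e-08; adjusted p = 0.135 with an estimated correlation). Idi1 (1.80 ± 0.40, edgeR adjusted p = 0.0288) was among those that rose, and Hmgcs1 (1.45 ± 0.37, edgeR adjusted p = 0.0609) and Msmo1 (1.22 ± 0.37, edgeR adjusted p = 0.134) did not pass. Of 20 monocyte genes, 3 rose, among them Cd177 and F13a1, and 2 fell, among them Thbs1 (-1.31 ± 0.27); adjusted over the list alone, 5 rose and 3 fell (camera adjusted p = 0.0508).

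Lists that did not pass in this class were interferon response (0 of 26 genes changed; camera adjusted p = 0.410), immediate early and dissociation stress genes (0 of 25; 0.240), fatty acid oxidation (0 of 9; 0.853), B cell activation (0 of 10; 0.240), mitochondrially encoded transcripts (0 of 13; 0.779), effector genes of T and natural killer cells (1 of 9, Ccl4; 0.474), YAP and TEAD targets (1 of 9, Axl; 0.944) and myofibroblast activation (1 of 5; 0.977). None of the 5 measured hepatocyte transcripts changed over all genes, 2 were lower adjusted over the list alone, and the list was lower (camera adjusted p = 0.0234; adjusted p = 0.239 with an estimated correlation). Lists of extracellular matrix, quiescent stellate cell, sinusoidal endothelial, bile acid and haemoglobin genes had fewer than 4 measured members, of which Ecm1 (-1.78 ± 0.27), Mrc1 (-2.24 ± 0.47) and Stab1 (-1.96 ± 0.43) fell. Hbb-bs also fell (-6.79 ± 1.62, edgeR adjusted p = 0.0410), but 4 cells of Control 1 held 98.7% of that library's haemoglobin UMIs in the class. With the preset correlation 11 of 21 lists changed, 10 lower and 1 higher, and with an estimated correlation 0 of 21 did.

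The mix of cells within the macrophage class differed too. At a finer resolution the class split into a cluster led by Ear2, Adgre4 and Ace (233 and 277 Control cells, 174 and 74 KO cells), a cluster led by Chil3 and F13a1 (149 and 148 Control, 142 and 82 KO) and a cluster led by C1q genes (86 and 48 Control, 6 and 2 KO). Ace of the Ear2-led cluster and Chil3 and F13a1 of the Chil3-led cluster belong to the monocyte gene list, so these cells may be monocytes. Refitted without the C1q-led cells, a choice made after seeing the data, 43 of 6749 genes changed, 9 higher and 34 lower. Of the 115 genes that fell in the class, 86 could be refitted, 85 had a negative fold change and 32 passed as lower. These genes were picked as lower in the same libraries and mostly the same cells, so negative signs were favoured beforehand. Emp1 (-4.31 ± 0.39, edgeR adjusted p = 1.91e-05), Hebp1 (-4.73 ± 0.50), C1qb (-3.37 ± 0.45), H2-Eb1 (-2.31 ± 0.32) and H2-Ab1 (-1.56 ± 0.26) still fell, and Hpgd (1.47 ± 0.25) still rose. Trem2 (-0.67 ± 0.26, edgeR adjusted p = 0.380), Apoe (-0.88 ± 0.22, edgeR adjusted p = 0.0892), Ccl4 (-0.83 ± 0.29, edgeR adjusted p = 0.305) and Cxcl2 (-0.69 ± 0.23, edgeR adjusted p = 0.278) did not pass. The MHC class II list (median -0.67; camera adjusted p = 2.02e-08; adjusted p = 0.539 with an estimated correlation) and the cholesterol list (median 1.05; camera adjusted p = 5.60e-08; adjusted p = 0.509 with an estimated correlation) still passed, as did the Kupffer cell, endothelial and lipid synthesis lists (adjusted p = 0.539, 0.539 and 0.573 with an estimated correlation). The lipid-associated (median -0.13; camera adjusted p = 0.119), profibrotic (0.05; 0.350), NF-kappaB (-0.23; 0.0502), cell cycle (-0.24; 0.119) and hepatocyte (-0.08; 0.350) lists no longer passed, and the acute phase list had too few measured members. The Ear2-led cluster alone gave 30 changed genes and the Chil3-led cluster alone 15.

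In T cell-like cells, 110 of 11476 genes changed, 35 higher and 75 lower in KO. Klrb1c, the natural killer receptor NK1.1, rose from 14.0 ± 4.58 to 46.6 ± 7.59 CPM (log2 1.84 ± 0.21, edgeR adjusted p = 0.00956), and Gm14085 (1.78 ± 0.21) and the deubiquitinase gene Usp28 (1.30 ± 0.17) rose too. The co-stimulatory receptor gene Tnfrsf4 fell from 20.7 ± 0.284 to 5.0 ± 0.370 CPM (log2 -2.06 ± 0.20, edgeR adjusted p = 0.00407). Cxcl2 (-3.57 ± 0.35) and the neutrophil gene S100a9 (-3.00 ± 0.31) fell, and neutrophil-like cells, which hold most S100a9 and had the highest Cxcl2 of the tested classes, had a lower share in KO in the main test. Cluster 7 held the largest part of Control T cell-like cells (20.4%) and cluster 13 of KO ones (23.6%). Tnfrsf4 was among the leading genes of cluster 8 (15.5% of Control and 7.54% of KO T cell-like cells). Gm14085 was among those of cluster 14 (13.1% and 21.75%). Whether these genes follow the mix of cells was not tested. Each library left out in turn moved the count by over 1.5 times, from 65 genes without KO 2 to 782 without Control 2, with 385 without Control 1 and a value between these without KO 1.

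In natural killer or innate lymphoid-like cells, 206 of 7912 genes changed, 90 higher and 116 lower. Gzmc, a granzyme of cytotoxic cells, fell from 71.5 ± 7.24 to 9.03 ± 0.805 CPM (log2 -2.93 ± 0.31, edgeR adjusted p = 1.74e-09). Cxcl2 (-4.59 ± 0.44, edgeR adjusted p = 7.92e-11) and the transcript AY036118 (-2.90 ± 0.30, edgeR adjusted p = 5.32e-10) fell as well. Cxcl2 was at 37.7 and 73.8 CPM in Control 1 and 2 here, against 16558 and 11340 CPM in neutrophil-like cells. The transcripts S100a8 (-2.56 ± 0.35), S100a9 (-2.26 ± 0.32) and Apoe (-3.20 ± 0.47) of other cells fell too, so free RNA was not excluded for Cxcl2. The 3 higher genes with the smallest p were the haemoglobin genes Hba-a1, Hbb-bs and Hbb-bt, but 1 cell of KO 1 held 99.8% and 2 cells of KO 2 held 98.6% of the haemoglobin UMIs of the class. With hepatocyte and haemoglobin genes left out, 200 genes changed. Cluster 3, led by Gm36723, Klrb1b and Ncr1, held 62.6% of the Control cells of this class, and cluster 16, led by Gzma, Klra8 and Klra4, held 67.5% of the KO cells. Leaving out Control 1, KO 1 or KO 2 gave 133, 118 or 15 changed genes, and DESeq2 gave 60.

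In B cell-like cells, 55 of 9907 genes changed, 14 higher and 41 lower. Gpr155, a cholesterol-sensing lysosomal protein, rose from 9.77 ± 1.46 to 25.2 ± 1.87 CPM (log2 1.45 ± 0.25, edgeR adjusted p = 0.0125), and Clec2i (0.77 ± 0.14) and Gm42722 (1.48 ± 0.28) rose. S100a9 (-2.99 ± 0.27, edgeR adjusted p = 2.62e-05), S100a8 (-3.23 ± 0.32) and Hbb-bt (-3.86 ± 0.40) fell, which are transcripts of neutrophils and red cells. In Control 1 and 2, 8 and 2 B cell-like cells held 97.7% and 99.4% of the haemoglobin UMIs. Cluster 10 held the largest part of Control B cell-like cells (56.2%) and cluster 12 of KO ones (45.4%). Leaving out Control 1, Control 2, KO 1 or KO 2 gave 83, 111, 122 or 26 changed genes, and DESeq2 gave 28.

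In conventional dendritic-like cells, of which the KO libraries had 56 and 54, 13 of 5910 genes changed, 9 higher and 4 lower. The interferon-induced chemokine gene Cxcl9 was at least 13.2-fold lower, with 163 UMIs in Control and 0 in KO (edgeR adjusted p = 0.00206). Ifitm1 fell with 186 UMIs in Control and 2 in KO, a ratio of 22.6 (counting interval 6.18 to 188), and the cytokine gene Il1b fell by 2.67 ± 0.49 on the log2 scale. The chemokine receptor gene Ccr7 (2.25 ± 0.39), which guides dendritic cells to lymph nodes, and Cd63 (2.02 ± 0.35) rose, as did the B cell gene Cd79a (3.42 ± 0.59), which had 2 UMIs in KO 1 and 52 in KO 2. Leaving out KO 1 or KO 2 gave 95 or 24 changed genes, and DESeq2 gave 3.

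In plasmacytoid dendritic-like cells, with 63, 43, 23 and 42 cells, 31 of 2691 genes changed, 25 higher and 6 lower. Ctla2a (log2 4.59 ± 0.60), Dusp2 (2.12 ± 0.28) and Emb (2.67 ± 0.37) rose (edgeR adjusted p = 0.00601 for each), and AY036118 (-3.67 ± 0.51), Ly6a (-1.46 ± 0.26) and Cd209d (-1.74 ± 0.33) fell. Genes of other cells rose with them: Nkg7, a gene of cytotoxic T and natural killer cells named after its value was seen, rose by 2.85 ± 0.58 on the log2 scale (edgeR adjusted p = 0.0358), with 10 and 77 UMIs in KO 1 and 2. Ctla2a, with 16 and 118 UMIs in KO 1 and 2 (207 and 453 CPM, against 26.5 and 5.87 CPM in Control 1 and 2), was also among the genes that led T cell-like cluster 13. Doublets were removed by another rule in KO 2, so T or natural killer transcripts within this class were not excluded. Leaving out Control 1 or KO 1 gave 70 or 113 changed genes, and DESeq2 gave 12. In neutrophil-like cells 0 of 1554 genes rose and 6 fell, among them the interferon-induced gene Isg15 (-2.07 ± 0.41, edgeR adjusted p = 0.0165), AY036118 (-2.76 ± 0.55) and Gm10800, which was at least 9.47-fold lower. DESeq2 gave 0 in neutrophil-like cells, and leaving out Control 1, Control 2 or KO 2 gave 20, 16 or 2. In cycling cell-like cells edgeR gave 0 changed genes of 5143 (323 at an unadjusted p under 0.05) and DESeq2 gave 1, and leaving out Control 1, Control 2, KO 1 or KO 2 gave 223, 17, 35 or 5.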

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

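The tests of whether KO effects differ between cell classes, the fits without C1q-led macrophages, and the tests on the lipid-associated and MHC class II lists were chosen only after the results were seen.

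The KO effect differed between macrophage-like cells and other classes in a model with the library as a block and a term for the difference (edgeR, Benjamini-Hochberg). It differed from T cell-like cells for 128 of 6706 genes, among them 45 of the 100 macrophage calls measured in both. It differed from B cell-like cells for 129 of 6556 genes (41 of 86 calls) and from natural killer or innate lymphoid-like cells for 68 of 6224 (22 of 74). A pair of genes passed in opposite directions in macrophage-like and natural killer or innate lymphoid-like cells. Cmklr1, a receptor for the chemoattractant chemerin, fell in macrophage-like cells (log2 -1.49; edgeR adjusted p = 0.0327) and rose in the other class (1.59; edgeR adjusted p = 0.0442), a difference of -3.16 (edgeR adjusted p = 0.00338). Hbb-bs differed by -13.19, and its counts came from a few cells in either class (4 of Control 1, 1 of KO 1 and 2 of KO 2). The mix of cells within these classes differed between the groups too. C1q-led macrophages were 86 and 48 cells in Control and 6 and 2 in KO. Cluster 16 held 37.4% of Control and 67.5% of KO natural killer or innate lymphoid-like cells. The model does not separate the mix from a change within cells, for Cmklr1 or for the counts above.

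The first pattern is the lower transcripts of macrophage-like cells. If fewer C1q-led cells in KO were the cause, the genes should lose their change without those cells: the 86 genes that could be refitted had a median of -1.21 (interquartile range 0.959), the MHC class II list -0.67 and the lipid-associated list -0.13. Fewer C1q-led cells and a change within cells cannot be told apart for the lipid-associated list, since Apoe, Spp1 and Lpl of that list led the removed cluster, so that its removal shrinks the list in either case. For the class as a whole they cannot be told apart either. Of the 115 genes that fell, those outside the 86 had too few counts without the C1q-led cells, 32 of the 86 still passed as lower, and the median lay between the bounds set beforehand. In the Ear2-led cluster alone the median was -1.22 (quartiles -1.85 and -0.75), with 21 of 65 genes still called, and in the Chil3-led cluster alone -0.78 (quartiles -1.39 and -0.59), with 11 of 66. The 115 genes were picked as lower in the same libraries and mostly the same cells, which favours negative medians in each of these fits. For MHC class II the rule could not tell fewer C1q-led cells from a change within cells, since the spread between genes (interquartile range 1.07) exceeded the shift. That spread is not the error of the shift, so the rule decides little. H2-Eb1, H2-Ab1 and C1qb still fell among the cells that were left. C1qb led the removed cluster, so cells of that cluster left behind, or their RNA, were not excluded for C1qb. If free RNA in all droplets were the cause, the genes should be as high in T cell-like cells: the median log2 ratio of Control macrophages to Control T cells was 5.09 (interquartile range 0.284) for the MHC class II genes that fell, which argues against it for these. That ratio covers only RNA shared by all droplets. Conventional dendritic-like cells fell from 7.14% of Control to 0.958% of KO cells, and their transcripts within the macrophage class were not tested. The median log2 ratio was 5.74 for the lipid-associated genes that fell and 3.68 for all 115, with interquartile ranges of 3.28 and 5.38. The median for all 115 lay past the bound set beforehand against free RNA. Of these genes, however, 30 had single ratios under the bound set for free RNA. The spread thus leaves free RNA open for part of them, and the loss of Cyr61 itself stays open as untested.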

How the results depend on the processing

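The fits on part of the macrophage clusters and the gene lists in other classes were tests chosen only after the results were seen. Ccn1 was lower under every alternative run, with edgeR adjusted p from 9.03e-39 to 0.0407 and 0.0933 with DESeq2 (log2 -5.33), the one setting where it did not pass. Relative log expression size factors left each of these counts within 1.5 times, as did TMM over the classes for shares. DESeq2 gave 61 changed genes in macrophage-like, 28 in B, 3 in conventional dendritic, 1 in cycling, 60 in natural killer or innate lymphoid, 0 in neutrophil and 12 in plasmacytoid dendritic cells, and 216 in the classes other than macrophages together; it also recovered fewer simulated changes. Without the filter on low counts these were 306, 182, 37, 103, 227, 12 and 101, with 573 in T cells and 1235 together. Leaving out hepatocyte and haemoglobin genes gave 36 in B cells, and at most 10% mitochondrial UMIs gave 13. At least 1000 UMIs gave 135 in natural killer or innate lymphoid and 0 in neutrophil cells. Keeping doublets gave 72 in macrophage-like, 86 in natural killer or innate lymphoid, 2 in neutrophil and 70 in plasmacytoid dendritic cells, and 3 changed shares, without conventional dendritic cells and the cluster with the leading genes of cluster 4 (edgeR adjusted p = 0.0587 for both). The neutrophil share did not pass at 1000 UMIs (edgeR adjusted p = 0.173) or at resolution 2.0 (0.0698). Resolution 2.0 gave 2 in conventional dendritic, 6 in cycling, 137 in natural killer or innate lymphoid and 12 in plasmacytoid dendritic cells. Without C1q-led cells macrophages gave 43 genes and 5 lists, and the Ear2-led and Chil3-led clusters alone gave 30 and 15 genes, from fewer cells. An estimated correlation gave 0 changed lists in macrophages and 0 in the other classes. Except where stated, the cause was not tested.

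The libraries share only replicate numbers: over the 2 pairs, deviations of same-numbered libraries correlated at 0.042 over all cells and from -0.04 to 0.177 in the classes, positive in 7 of 8 classes and over 0.1 in 4. The labels state no pairing and 2 pairs can neither show nor exclude one, so the block is given only as an alternative. With the number as a block, 383 genes changed in macrophage-like, 448 in B, 47 in conventional dendritic, 5 in cycling, 0 in neutrophil and 516 in T cells, 1343 in the classes other than macrophages together, and 1 share. Leaving out 1 library, where the lone library is assumed to vary like the other group, gave 129 to 302 genes in macrophage-like, 26 to 122 in B, 13 to 95 in conventional dendritic, 5 to 223 in cycling, 15 to 167 in natural killer or innate lymphoid, 2 to 20 in neutrophil, 30 to 113 in plasmacytoid dendritic and 65 to 782 in T cells, 174 to 1136 together, 0 to 9 shares and log2 values of Ccn1 from -10.60 (its KO count then 0) to -4.28. Syk (0.02) turned to -0.061 at 10% mitochondrial UMIs, -0.043 with doublets kept and -0.072 without C1q-led cells, and ranged from -0.19 to 0.248 with 1 library left out, where Nfkb1 ranged from -0.017 to 0.385, none past the threshold. Pdgfb (-1.14) gained a call without the filter on low counts (-1.13; edgeR adjusted p = 0.0389), with the block (-1.13; 0.0158), at 10% mitochondrial UMIs (-1.65; 0.0418) and without KO 2 (-2.63; 5.24e-05). Kupffer, stellate or fibroblast, endothelial and hepatocyte results, and gene lists in those classes, gave no values because cells were too few; plasmacytoid dendritic cells were too few at 10% mitochondrial UMIs and at 1000 UMIs, where the classes together lack them.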

Other observations

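The gene lists in classes other than macrophages, and the tests on hepatocyte yield, on AY036118, Lars2 and Gm42418, and on chromosome windows, were chosen only after the results were seen.

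The cholesterol synthesis and uptake list was higher in KO in most classes tested. Besides macrophage-like cells it passed in B cell-like (median log2 0.50; camera adjusted p = 5.36e-06), conventional dendritic-like (0.93; 1.21e-06), natural killer or innate lymphoid-like (0.56; 0.00693), T cell-like (0.18; 0.0133) and cycling cell-like cells (0.39; 0.0178), and not in plasmacytoid dendritic-like cells (0.33; 0.286). The adjusted p was 0.520 with an estimated correlation in each of the 5. Few single members passed, with 2 of 11 higher in natural killer or innate lymphoid-like cells and 0 in the other 4 classes; adjusted over the list alone, 4 rose in natural killer or innate lymphoid-like and 4 in B cell-like cells.

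The interferon response list was lower in neutrophil-like (median -1.39; camera adjusted p = 3.22e-07), plasmacytoid dendritic-like (-0.79; 0.00409), B cell-like (-0.31; 0.00650), conventional dendritic-like (-0.23; 0.000661) and T cell-like cells (-0.15; 0.0338), each with adjusted p between 0.520 and 0.763 with an estimated correlation. The MHC class II list was lower in natural killer or innate lymphoid-like (-1.08; 2.60e-08), plasmacytoid dendritic-like (-0.82; 4.24e-05), conventional dendritic-like (-0.57; 3.30e-05) and cycling cell-like cells (-0.81; 0.00297), with adjusted p of 0.520, 0.520, 0.520 and 0.655 with an estimated correlation. Single members that passed as lower were few for the interferon list, with 1 of 7, 2 of 9, 0 of 24, 1 of 20 and 0 of 26 in the order given. For MHC class II they were 5 of 8, 0 of 9, 0 of 14 and 0 of 8. In natural killer or innate lymphoid-like cells Apoe, Cxcl2 and S100a8 of other cells fell too. H2-Eb1 was at 92.2 CPM in the Control cells of this class and at 5872 CPM in Control conventional dendritic-like cells, whose share fell from 7.14% to 0.958%. Free RNA was not tested for this list outside macrophages and stays open. NF-kappaB targets were lower in B cell-like (-0.24; 4.83e-05), neutrophil-like (-0.37; 0.0133), T cell-like (-0.01; 0.0250) and natural killer or innate lymphoid-like cells (-0.04; 0.0285), with adjusted p of 0.520, 0.676, 0.707 and 0.654 with an estimated correlation. Few members carried this, with 2 of 26, 0 of 17, 3 of 24 and 3 of 23 lower, and Cxcl2, Bcl2a1b and Bcl2a1d were the 3 in both T and natural killer or innate lymphoid-like cells. Cxcl2 stood at 16558 and 11340 CPM in Control neutrophil-like cells and at 73.8 CPM or lower in the Control T, B and natural killer or innate lymphoid-like cells, where S100a8 and S100a9 fell as well, so free RNA stays open for it. They were higher in plasmacytoid dendritic-like cells (median 1.04, 3 of 15 rose, 7 adjusted over the list alone; camera adjusted p = 2.82e-10; adjusted p = 0.520 with an estimated correlation). In that class effector genes of T and natural killer cells were higher too (median 2.07, 2 of 7 rose, 5 adjusted over the list alone; camera adjusted p = 5.36e-06; adjusted p = 0.520 with an estimated correlation), as were B cell activation genes (0.88; 0.0245; adjusted p = 0.520 with an estimated correlation), of which 1 of 6 rose, or 3 rose and 2 fell adjusted over the list alone. The NF-kappaB and effector lists share Ccl3, Ccl4, Ccl5 and Tnf, so transcripts of other cells in this class were not excluded. Lists not named above passed too. In T cell-like cells lipid-associated macrophage genes (median -0.33, camera adjusted p = 7.81e-05), hepatocyte transcripts (-1.49, 0.00136) and effector genes (-0.45, 9.32e-05) were lower. Mitochondrially encoded transcripts were higher in T cell-like (0.53, camera adjusted p = 0.00105) and conventional dendritic-like cells (0.35, 0.0343) and did not pass elsewhere. Over these classes 43 of 117 list tests passed, 15 higher and 28 lower, and 0 did with an estimated correlation.

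The second pattern is the near absence of cluster 4 from the KO libraries. Its cells carried mesothelial genes, with Upk3b at 838 CPM, Msln at 446 and Wt1 at 286, and no UMI of the stellate cell gene Lrat, so a candidate explanation is that less of the liver surface was sampled in KO. If so, the C1q-led macrophages should carry genes of peritoneal macrophages. In Control libraries, 4 of 8 such genes were over 2-fold higher in them than in the other finer clusters of the class. Counts were few (Prg4 23 UMIs against 2, Alox15 13 against 0, Rarb 5 against 2, Gata6 4 against 0). These genes were not compared with cluster 4, so RNA of its cells in the C1q-led droplets was not excluded. If all non-immune cells had a lower yield in KO, hepatocyte-like cells should be fewer too, but their share was 4.69 times higher in KO. They were 6 and 11 Control and 56 and 28 KO barcodes, with a median of 0.0% mitochondrial UMIs and 930 UMIs. Intact hepatocytes were thus not shown, and no named endothelial or stellate cluster was there to compare, so this test cannot decide. A loss of these cells through the lack of Cyr61 was not tested and stays open.

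The third pattern is 72 genes that passed in the same direction in at least 2 classes, 18 higher and 54 lower. S100a8 and S100a9 fell in T, B and natural killer or innate lymphoid-like cells, where their log2 ratio to each other lay close to that in neutrophil-like cells (largest difference -0.0269), so free RNA of neutrophils may account for them. Doublets with neutrophils would carry the same ratio, so the match does not tell free RNA from doublets. A lower neutrophil share alone falls short of the size: the share differed by -1.09 on the log2 scale and the genes by 0.02 and 0.06 within neutrophil-like cells, against -2.26 to -3.23 in these classes. AY036118, Lars2 and Gm42418 had a negative fitted fold change in 24 of 24 tests over 8 classes, 14 of them past the threshold. This may reflect a property of whole libraries, such as handling, that the design confounds with the groups. The classes share the same libraries, so the tests are not separate support. In conventional dendritic-like cells Lars2 in KO 1 (1695 CPM) lay above Control 1 and 2 (1093 and 1334 CPM). Over 10 Mb windows the genes gathered most in chromosome 6, 130 to 140 Mb (Emp1, Klra3, Klra9 and Styk1, adjusted Fisher's exact p = 0.00503). The adjustment covered only the 48 windows that held such a gene, which makes it too lenient. A segment of different parental origin is a candidate explanation for part of the pattern. The higher Klra genes may also follow the mix of cells, since Klra8 and Klra9 were among the leading genes of natural killer cluster 16 (37.4% of Control and 67.5% of KO cells of its class) and Klra9 of T cell-like cluster 1 (8.45% and 16.4%). Another 3 windows passed under the same lenient adjustment (adjusted Fisher's exact p = 0.0125, 0.0125 and 0.0486), so their calls are uncertain. They held histone, Bcl2a1 or MHC genes among others, and gene families were not told from segments. Hebp1 (135137522 to 135198022) and Emp1 (135362545 to 135383173), which kept falling without C1q-led macrophages, lie close together in the chromosome 6 window, and counts of the Klra family are uncertain because its members are near copies. Klrb1c (128778485 to 128789215) and Clec2i (128887588 to 128898167), which rose in T and B cell-like cells, lie just below its lower edge. The window of 120 to 130 Mb, with Klrb1c and Il17ra, did not pass (adjusted Fisher's exact p = 0.341). Whether a segment of different origin reaches Klrb1c and Clec2i was not tested.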
